A study of Mus musculus with 4 samples.

How the data were processed

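Gene expression was measured in mouse cells on Agilent whole-genome oligonucleotide arrays, with 1 array per sample and 4 arrays in all. Whole prostates were taken from 8-week-old C57BL/6J mice whose prostate epithelium lacks Pten, made into a single-cell suspension, stained with antibodies and sorted by flow cytometry, per the labels' protocols. A pair of fractions was profiled: Gr-1+ myeloid cells, also named CD11b+ in the series title, and epithelial cells. Each fraction has 2 samples, and each sample is a pool of cells from 3 mice, from 2 independent experiments. Total RNA was amplified and labelled with Cy3 from 100 ng, per the labels' protocols.

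The scanner files hold spot intensity values that Agilent Feature Extraction 10.7.3.1 made, per the file headers, for array design 028005 with 1 colour. Its processed intensity had been detrended across the slide and background-subtracted, and had not been normalized between arrays, per the file headers. The authors also deposited a table of log2 values for the same arrays. R 3.0.2 and limma are listed in the submitters' processing notes without a role, and the authors' normalization steps are not given in the sources used here. Set against the scanner files, the order of the authors' values on each array was that of the median spot signal minus its local background (Spearman rho 1 over the probes with 1 spot that have a value), and their cells were empty where Feature Extraction called the spot no brighter than background. The column medians of the authors' log2 values were 8.57 and 8.29 for epithelial 1 and 2 and 8.12 and 8.19 for myeloid 1 and 2. These values rose with signal and were not centred per gene, and they served as an alternative.

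Each array held 62976 spots, of which 59305 were not controls. Repeat spots of a probe were averaged, outlier spots were left out, and 5 probes lost all their spots that way, which left 55676 probes. The gene names of the array design were updated through the accession of each probe with a RefSeq table for GRCm38.p6, used only for names. That table held the accession of 27654 probes. The name in the files was kept for the other 28022, and 27240 probes had only a clone-type name. Probe positions are those of the file headers' build, mm9, and whether a probe lies in an exon or an untranslated region of that build was not analysed here.

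The main values were log2 of the processed intensity minus the array's own 75th percentile of it. Probes were kept when well above background on both arrays of at least 1 group, which kept 26274 probes. The probe with the highest mean over the 4 arrays stood for its gene, which gave 19274 genes, 11939 of them with a gene symbol and the rest with clone or transcript names. Myeloid and epithelial arrays were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the contrast myeloid minus epithelial, no covariate, Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. Tables were handled with data.table (version 1.17.8) and figures drawn with matplotlib 3.10.9. A gene not well above background on either array of 1 group has only a bound there: its fold is given as "at least", from the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value of any probe well above background.

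A total of 32 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. Camera asks whether a list's genes differ more than the other genes do. The p-value of fry asks whether the genes of a list move, on balance, one way, its mixed p-value whether they change in either direction, and neither compares a list with other genes. The grouping, the test, the lists, the rule for named genes and all alternatives but 1 were set before the data were examined. The rule names the genes of the design (Pten, sorting markers and IL-1 ligands, antagonist and receptors), the 8 genes with the largest difference in each direction among called genes well above background on all 4 arrays, the 6 with the largest bound in each direction, and the 3 largest called members of each list with the largest going the other way. Other members are named where they complete a list or go against its name, and those were chosen after their values were seen.

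Alternatives were quantile normalization, median scaling, the 75th percentile over probes detected on all 4 arrays, normexp background correction with an offset of 50 followed by either scaling, the authors' values, no filter on dim probes, a filter on all 4 arrays, the mean of a gene's probes, a trended and robust prior, the replicate number as a block, and leaving out each array in turn. Under 50% of the probes were well above background on each array, so the percentile over detected probes is also given. Leaving out probes with a simple repeat was added after the data were seen. The scripts were tested on simulated data over 26274 probes. Probes were drawn independently, each with a spread shared by both groups and taken from a distribution fitted to these arrays. With 50 probes changed at each size, 0%, 2%, 68% and 84% of those changed by 1, 2, 4 and 6 log2 units were recovered and 4 of 81 calls were false. With far more probes changed, as between cell types, 34%, 85.1%, 97.2% and 99% were recovered and 3.31% of calls were false. A simulated list that moved was called (adjusted p = 3.6e-37 by camera of limma), and 0 of 20 unmoved lists were. The real fractions differ in spread (median SD per gene 0.10 in myeloid and 0.36 in epithelial cells). Genes of real lists can be correlated (estimated at 0.774 for basal markers). The simulation held neither trait, so it does not show how many false gene or list calls arise under them.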

Results

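The data are expression profiles of sorted cells from the prostates of 8-week-old mice with Pten deleted in the prostate epithelium, a model of prostate tumours. Gr-1+ myeloid cells, a gate that takes in granulocytes and some monocytes, were compared with epithelial cells of the same organ, with 2 arrays per fraction and cells of 3 mice pooled for each. The comparison asks which genes tell the myeloid cells apart from the epithelium they infiltrate. All 4 arrays lay on 1 slide and in 1 scan, with the epithelial arrays in slide row 1 and the myeloid arrays in slide row 2, so slide row and cell type cannot be told apart. Of 55676 probes, 20937 (37.6%) and 24182 (43.4%) were well above background on epithelial 1 and 2, and 26906 (48.3%) and 25802 (46.3%) on myeloid 1 and 2. No probe was saturated. The 75th percentile of signal was 147 and 182 on the epithelial arrays and 207 and 216 on the myeloid arrays.

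Pten, the phosphatase gene that these mice lack in the prostate epithelium, had 3 probes on chromosome 19 (mm9). The brightest, at 32892510 to 32894351, read 1.68 and 1.24 on epithelial 1 and 2 and 2.27 and 2.40 on myeloid 1 and 2, in log2 units relative to the array's 75th percentile. That difference of 0.88 ± 0.27 (SE) did not pass (adjusted p = 0.0693, limma). The probe at 32883442 to 32883501 was higher in myeloid cells, by 1.68 ± 0.33 (adjusted p = 0.0255, limma, in a fit of all kept probes). The probe at 32899714 to 32899773 was not well above background on any array. Which exons are deleted is not given in the sources used here, so these probes do not check the labels.

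Leukocyte and epithelial markers separated the fractions, though not every sorting marker did. Ptprc, the pan-leukocyte surface antigen CD45, was higher in myeloid cells by 5.55 ± 0.41 (adjusted p = 0.0047, limma), and 28 of 30 pan-leukocyte genes were higher with 0 lower, Plek (8.75 ± 1.48), Vav1 (7.67 ± 1.49) and the signalling adaptor Tyrobp (7.49 ± 1.27) leading. All 30 were higher when adjusted over the list alone, and the list differed from other genes (median 4.98, or 4.22 with 13 members at their bounds). Camera gave the list adjusted p = 2.27e-14 (adjusted p = 0.256 with an estimated correlation). Ptprc, Plek, Vav1 and Tyrobp were well above background on only 1 epithelial array. With the other array at the lowest value of a probe well above background, Plek was at 8.07 and Vav1 at 7.11, and Ptprc and Tyrobp did not change. The keratins Krt18 and Krt8, filament proteins of luminal epithelium, were lower in myeloid cells by 2.99 ± 0.65 and 2.70 ± 0.68 on the log2 scale (adjusted p = 0.0329 and 0.0458, limma). The other probe of Krt8 had a difference of -2.10 ± 0.68 that did not pass (adjusted p = 0.0771, limma, in a fit of all kept probes). The Krt8 call also ended under other settings, such as quantile normalization (adjusted p = 0.0587, limma). Epcam, a surface adhesion protein of epithelium, had a difference of -2.41 ± 0.71 that did not pass (adjusted p = 0.0646, limma), with 4.29 and 2.30 on the epithelial arrays and 0.70 and 1.07 on the myeloid arrays. Epcam passed with the replicate number as a block (adjusted p = 0.0197, limma). For Itgam, which encodes CD11b, the brightest probe had a difference of 0.66 ± 0.24 that did not pass (adjusted p = 0.103, limma). The other probes of Itgam were higher in myeloid cells by 3.96 ± 0.28 and 3.54 ± 0.25 (adjusted p = 0.00376 and 0.00378). Of the genes for the Gr-1 antigens, Ly6g had a difference of -1.27 ± 0.37 that did not pass (adjusted p = 0.0628, limma) but was called lower in myeloid cells with median scaling (-1.39) and the authors' values (-1.47), and Ly6c1 was lower in the myeloid cells by -1.92 ± 0.26 (adjusted p = 0.012, limma). Ly6c2, also a planned sorting marker, had no probe under that name. Ly6g rests on a single probe, at -1.07 on average in myeloid cells, where the lowest detected values were -2.23 and -2.19. Of 34 neutrophil genes, a list that holds Ly6g, 20 were higher in the same cells and 1 was lower.

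**Figure D1:**
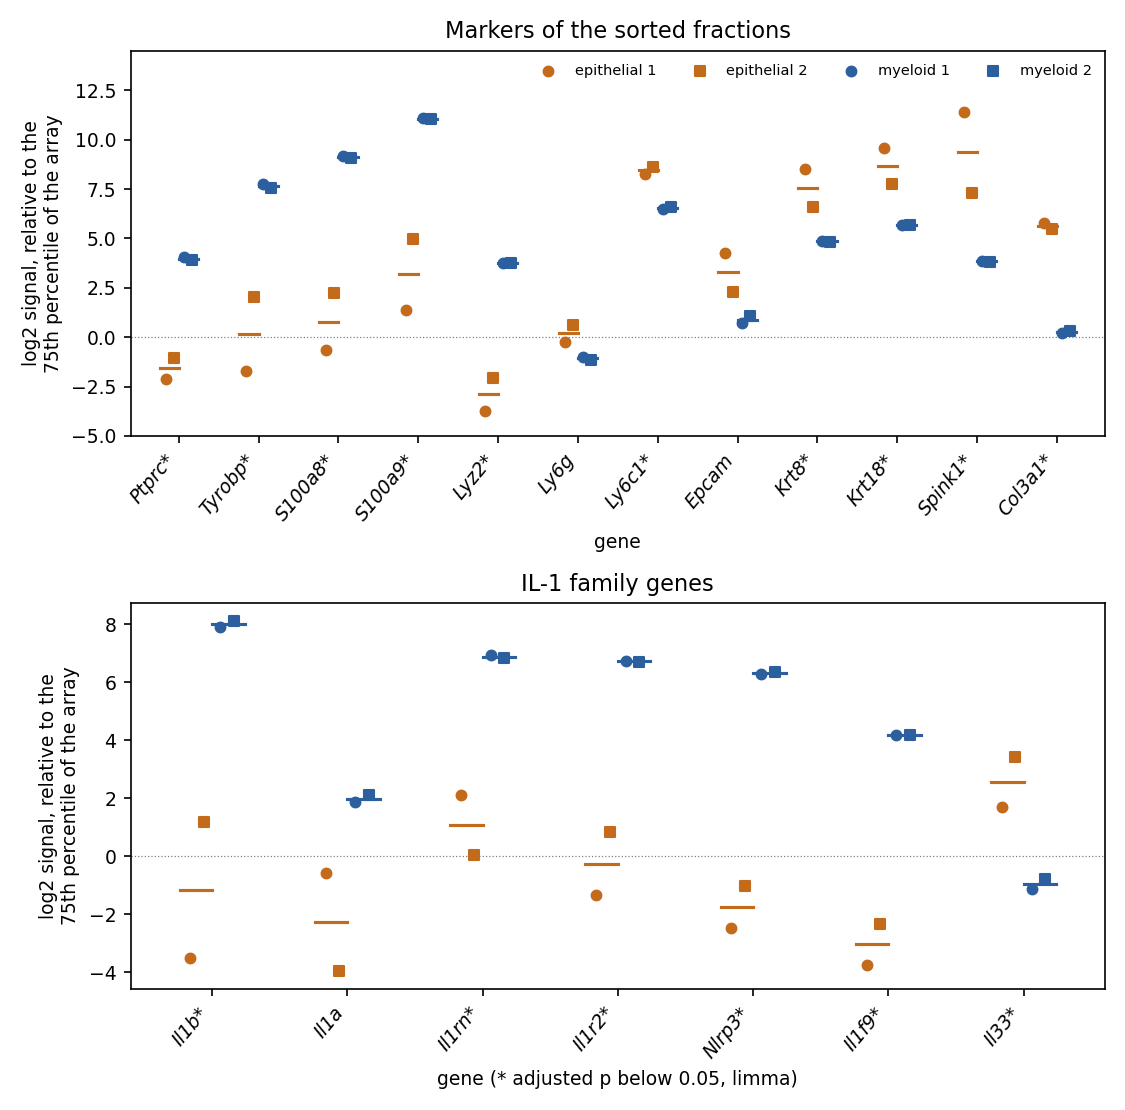
Log2 signal of marker genes (upper panel) and IL-1 family genes (lower panel) on each of the 4 arrays, relative to the array's 75th percentile (vertical axis), by gene (horizontal axis). Points are arrays, short lines are group means of 2 arrays, and an asterisk marks an adjusted p below 0.05 by limma: S100a9 lies at 11.06 on average in myeloid cells and 3.18 in epithelial cells, with the epithelial arrays far apart, and Krt18 at 5.68 and 8.68.

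Across all genes, 5849 of 19274 differed between the fractions, 2758 higher in myeloid and 3091 higher in epithelial cells, and 5576 of them by at least 2-fold. With genes below background in 1 fraction counted at their bound, 306 genes were at least 16-fold higher in myeloid cells and 63 in epithelium. Of the genes called, 1092 were not well above background on either epithelial array and 573 on neither myeloid array. Among genes well above background on all 4 arrays, those with the largest excess in myeloid cells were S100a8 (8.31 ± 1.00) and S100a9 (7.88 ± 1.22), which encode the calprotectin subunits of neutrophils, Acod1 (8.06 ± 0.80), which makes itaconate in activated macrophages, and Cyp4f18 (7.52 ± 0.40), followed by the noncoding RNA Mirt1 (6.97), the immunoglobulin-like receptor Lilr4b (6.75), Sh2d3c (6.67) and the Fc receptor chain Fcer1g (6.58). Among genes not well above background on either epithelial array, Mirt2 was at least 193-fold, Cstdc4 at least 145-fold, Retnlg at least 143-fold, the stefin gene Stfa2l1 at least 132-fold, the platelet-activating factor receptor Ptafr at least 97.7-fold and the survival gene Bcl2a1c at least 93.3-fold higher in myeloid cells. On the epithelial side the leading genes were the trypsin inhibitor Spink1 (-5.53 ± 1.38), the retinal dehydrogenase Aldh1a3 (-5.42 ± 1.26), the collagen Col3a1 (-5.36 ± 0.24), the Wnt inhibitor Wif1 (-5.21 ± 0.69) and the prostate secretory genes Sbp (-5.06 ± 1.13) and Defb50 (-4.68 ± 0.92), with Akap12 (-4.66) and Mfap4 (-4.63). Nsg1 was at least 29.7-fold, Trnp1 at least 17.9-fold, the stromelysin Mmp3 at least 17.6-fold, the tachykinin gene Tac1 at least 16.9-fold, and the collagens Col6a3 and Col5a1 at least 16.4-fold and 16.3-fold higher in the epithelial fraction. Adjusted p-values of these 28 genes lay at or below 0.0453 by limma. Col3a1, Col6a3 and Col5a1 are among the fibroblast and matrix markers, of which 17 of 21 were higher in that fraction. Whether epithelial cells or stromal cells in the fraction express them was not tested.

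Some ligands and inhibitors of the IL-1 family set the fractions apart, though 15 of 26 members tested did not pass. Il1b, the secreted inflammatory cytokine (probe on chromosome 2, 129190347 to 129190406), was higher in myeloid cells by 9.17 ± 1.59 (adjusted p = 0.0203, limma), at 7.89 and 8.12 on the myeloid arrays and -3.52 and 1.20 on the epithelial arrays. The antagonist gene Il1rn (chromosome 2, 24205094 to 24205153) was higher by 5.81 ± 0.73 (56.1-fold, adjusted p = 0.0108, limma), at 6.88 ± 0.07 (SD, n = 2) against 1.08 ± 1.48 in epithelium. The decoy receptor gene Il1r2 (chromosome 1, 40180014 to 40180073) was higher by 6.97 ± 0.76 (adjusted p = 0.00821, limma). The inflammasome sensor Nlrp3 was higher by 8.08 ± 0.53, and Il1f9, which encodes IL-36 gamma, was at least 76.3-fold higher. Il33, an alarmin of barrier and stromal cells, was the single member called higher in epithelium (-3.52 ± 0.62, adjusted p = 0.0212, limma). Il1a had a difference of 4.26 ± 1.15 that did not pass (adjusted p = 0.0532, limma), with the epithelial arrays at -0.59 and -3.97 and the myeloid arrays at 1.87 and 2.10. It passed with normexp, with the authors' values and with the replicate number as a block (adjusted p = 0.00713 with the block, limma). Il1r1, the signalling receptor, was well above background on 1 array of each fraction and was not kept. Il1b, Il1r2, Nlrp3 and Il1a were well above background on only 1 epithelial array, and with the other at that floor the differences were 8.51, 6.97, 7.94 and 3.26. Of 26 members tested, 10 were higher and 1 lower in myeloid cells and 15 did not pass. Adjusted over the list alone, 12 were higher and 2 lower. The list median was 1.44, or 1.28 with 5 members at their bounds, and camera gave an adjusted p = 0.000621 (adjusted p = 0.256 with an estimated correlation). Restricted to genes well above background on all 4 arrays, 4 members were higher and the list did not pass (adjusted p = 0.0594, camera of limma).

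Most monocyte and macrophage markers and 20 of 34 neutrophil genes were higher in the Gr-1+ fraction than in epithelium. Of the 32 lists, camera called 13 higher in myeloid and 10 higher in epithelial cells, and with an estimated correlation none held. Of 34 neutrophil granule and marker genes, 20 were higher in myeloid cells and 1 was lower, the annexin gene Anxa1 (-1.37 ± 0.23), and adjusted over the list alone 21 were higher and 2 lower (median 2.52, or 1.67 with 14 members at their bounds). The camera test returned adjusted p = 1.02e-07 (adjusted p = 0.207 with an estimated correlation). The primary granule genes Mpo (1.84), Elane (0.24), Prtn3 (0.45) and Ctsg (0.47, not well above background on either epithelial array) did not pass. Of 28 monocyte and macrophage markers, 21 were higher and 1, Ly6c1, was lower, with the lectin receptors Clec4e (9.89 ± 1.16) and Clec4d (9.06 ± 1.25) leading and the lysozyme gene Lyz2 at least 57.8-fold higher. Adjusted over the list alone, 23 were higher and 1 lower (median 4.85, or 4.71 with 7 members at their bounds). By camera the list had adjusted p = 3.29e-08 (adjusted p = 0.395 with an estimated correlation). Of 27 genes tied to suppressor functions of myeloid cells, 18 were higher and 1 lower (19 and 1 adjusted over the list alone, median 4.23, or 3.16 with 7 members at their bounds, camera adjusted p = 3.29e-08, adjusted p = 0.207 with an estimated correlation). They included the NADPH oxidase subunits Ncf4 (7.18 ± 0.65) and Ncf2 (6.86 ± 0.88), the cystine transporter Slc7a11 (at least 18.0-fold), Cd274, which encodes PD-L1 (5.35), and Arg2 (4.97), while Tnfrsf10b, a death receptor, was higher in epithelium (-2.71 ± 0.57). Arg1 (-0.48) and Nos2 (-0.15), the enzymes most often used to mark such cells, did not pass. Mpo, Prtn3, Clec4e, Clec4d, Ncf4, Ncf2, Cd274 and Arg2 were well above background on only 1 epithelial array, and with the other at its floor Clec4e was at 9.06, Clec4d at 9.05, Ncf2 at 6.23 and Mpo at 1.37, the others unchanged.

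Most receptors for chemokines and colony-stimulating factors, and 12 of 24 pattern recognition receptors, were higher in the myeloid cells. Of 26 chemokine and colony-stimulating factor receptors, 21 were higher and 1 lower, and 22 and 1 when adjusted over the list alone (median 3.98, or 2.89 with 13 members at their bounds). In the camera test it had adjusted p = 1.57e-10 (adjusted p = 0.207 with an estimated correlation). The formyl peptide receptor Fpr2 was at least 59.0-fold, and the neutrophil chemokine receptor Cxcr1 at least 57.2-fold higher, Ccr7 was higher by 5.90 ± 0.81, and the scavenging receptor Ackr3 was at least 6.98-fold higher in epithelium. Of 24 pattern recognition receptors, 12 were higher in myeloid cells and 0 lower, with Clec7a, the beta-glucan receptor, at 8.38 ± 1.03, and adjusted over the list alone 14 were higher and 2 lower. For the list, camera gave adjusted p = 6.28e-06 (adjusted p = 0.207 with an estimated correlation). Chemokines themselves were split, with 10 of 28 higher in myeloid cells and 6 in epithelium, and 12 and 7 when adjusted over the list alone (camera adjusted p = 0.58). Ccl3 (9.12 ± 1.72) and Ccl4 (8.48 ± 1.38), ligands for monocytes and lymphocytes, and Ccl6 (5.70 ± 0.81) were higher in myeloid cells, and the eosinophil attractant Ccl11 was at least 6.49-fold higher in epithelium, as were Cxcl14 (-3.76) and the neutrophil attractant Cxcl1 (-1.85). The chemokine median was -0.13 and the mean 1.02, so the list has no single direction. Of 15 genes of MHC class II presentation, 12 were higher and 0 lower, 13 adjusted over the list alone, with H2-Ab1 at 5.91 ± 1.32, H2-Eb1 at 5.79 ± 1.47 and the costimulator Cd86 at least 20.5-fold higher (median 4.37, or 3.86 with 3 members at their bounds). Camera gave the list adjusted p = 2.81e-05 (adjusted p = 0.395 with an estimated correlation). Of 36 interferon-stimulated genes, 12 were higher and 1, Ifi44 (-1.92 ± 0.22), was lower, and 14 and 1 adjusted over the list alone (median 0.95). The camera test returned adjusted p = 0.00249 (adjusted p = 0.395 with an estimated correlation). Rsad2 (3.19 ± 0.26), Oas3 (2.96 ± 0.48) and Isg20 (2.72 ± 0.22) led that list. Ccr7, Clec7a, Ccl3, Ccl4, Ccl6 and Oas3 were well above background on only 1 epithelial array, and with the other at its floor Ccr7 was at 5.71, Clec7a at 7.65 and Ccl3 at 8.45, the others unchanged.

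**Figure D2:**
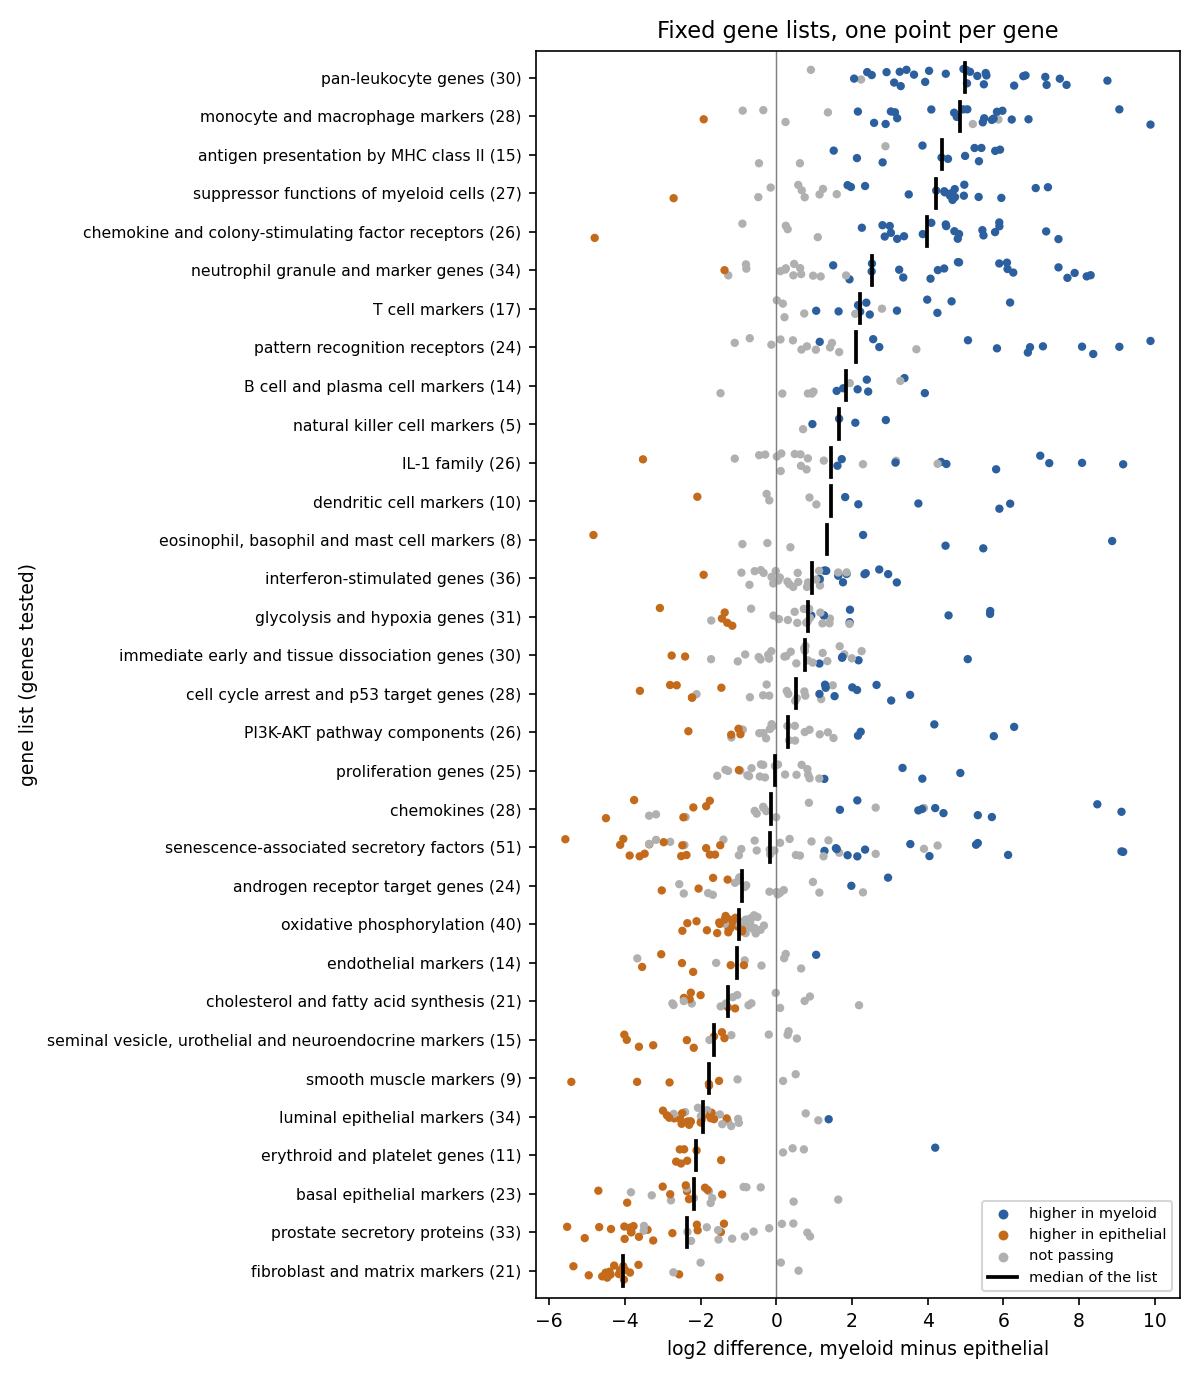
Log2 difference, myeloid minus epithelial (horizontal axis), of each tested gene of the 32 gene lists (vertical axis, number of genes tested in brackets). Each point is a gene, blue or orange where its adjusted p by limma was below 0.05, and black bars are list medians, from 4.98 for pan-leukocyte genes to -4.04 for fibroblast and matrix markers.

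Of the markers measured, most luminal, prostate secretory, fibroblast and smooth muscle genes, with 10 of 23 basal and 6 of 14 endothelial genes, were called higher in the epithelial fraction. Other members were too dim in both fractions to be kept. They were 3 luminal markers (Ar and Nkx3-1 among them), 8 secretory genes (Pbsn among them), 6 smooth muscle markers (Myh11, Cnn1 and Des among them) and 6 endothelial markers (Cdh5 and Tek among them). Of 34 luminal epithelial markers, 19 were higher there and 1, the tetraspanin gene Cd9 (1.38 ± 0.28), was higher in myeloid cells, and adjusted over the list alone 27 and 1 (median -1.95). By camera the list had adjusted p = 4.04e-07 (adjusted p = 0.442 with an estimated correlation). The tight junction genes Cldn3 (-2.89 ± 0.62) and Cldn7 (-2.83 ± 0.67) followed Krt18. Luminal transcripts were still measured in the myeloid fraction, with 33 of the 34 well above background on both myeloid arrays. Of 33 prostate secretory proteins, 18 were higher in epithelium and 0 in myeloid cells, 22 and 1 adjusted over the list alone (median -2.35, or -2.25 with 4 members at their bounds). In the camera test it had adjusted p = 6.28e-06 (adjusted p = 0.207 with an estimated correlation). Of 23 basal epithelial markers, 10 were higher in epithelium, 15 adjusted over the list alone, with Cav1 at least 7.11-fold, the growth factor receptor Egfr at -3.94 ± 0.36 and Krt17 at -3.0 ± 0.73 (median -2.18). For the list, camera gave adjusted p = 2.81e-05 (adjusted p = 0.445 with an estimated correlation). Among the lists higher in the epithelial fraction, fibroblast and matrix markers had the largest median difference, with 17 of 21 higher in the epithelial fraction, 18 adjusted over the list alone, among them Col3a1, Col6a3 and Fstl1 (-4.60 ± 0.62), and a median of -4.04, or -4.02 with 4 members at their bounds. Camera gave the list adjusted p = 4.8e-08 (adjusted p = 0.395 with an estimated correlation). Of 9 smooth muscle markers 6 were higher there, with the same 6 adjusted over the list alone, led by Cald1 (at least 10.5-fold), Myl9 (-3.68 ± 0.66) and Tpm2 (-2.82 ± 0.27). The camera test returned adjusted p = 0.00394 (adjusted p = 0.286 with an estimated correlation). Of 14 endothelial markers 6 were higher in the epithelial fraction and 1, Vwf (1.05 ± 0.24), in the myeloid fraction, 9 and 1 adjusted over the list alone. Robo4 (-3.55 ± 0.32), Egfl7 (-3.04 ± 0.33) and Ptprb (-2.49 ± 0.53) were among them. By camera the list had adjusted p = 0.0179 (adjusted p = 0.286 with an estimated correlation). Of 15 seminal vesicle, urothelial and neuroendocrine markers 9 were higher in the epithelial fraction, 11 adjusted over the list alone, chiefly the seminal vesicle secretory genes Svs4 (-4.02 ± 0.73), Svs1 (-3.95 ± 1.01) and Svs5 (-3.63 ± 0.65). In the camera test it had adjusted p = 0.00195 (adjusted p = 0.256 with an estimated correlation). Of 11 erythroid and platelet genes 7 were higher there, and 7 and 2 adjusted over the list alone, including the globins Hba-a1 (-2.65 ± 0.34) and Hbb-bt (-2.55 ± 0.22), while the platelet chemokine gene Pf4, which macrophages also express, was higher in myeloid cells (4.2 ± 0.51). For the list, camera gave adjusted p = 0.0265 (adjusted p = 0.457 with an estimated correlation). With genes well above background on all 4 arrays the endothelial (adjusted p = 0.2) and smooth muscle lists (adjusted p = 0.0951) did not pass. Robo4 was well above background on only 1 myeloid array, and Pf4 on only 1 epithelial array (3.99 with the other at its floor, Robo4 unchanged).

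Those lymphocyte transcripts that passed were higher in the Gr-1+ fraction than in epithelium. They were 11 of 17 T cell, 7 of 14 B and plasma cell and 4 of 5 natural killer markers measured, with 8 natural killer markers not kept. Of 17 T cell markers, 11 were higher and 0 lower, 13 adjusted over the list alone, with Cd3d, a chain of the T cell receptor complex, at least 33.6-fold, Cd2 at 4.63 ± 0.77 and the costimulator Icos at least 5.58-fold (median 2.22, or 2.09 with 5 members at their bounds). Camera gave the list adjusted p = 6.28e-06 (adjusted p = 0.256 with an estimated correlation). Of 14 B cell and plasma cell markers, 7 were higher, 11 adjusted over the list alone, with Cd79b at 3.92 ± 0.49, Ms4a1 at least 3.50-fold and Mzb1 at least 2.25-fold. The camera test returned adjusted p = 0.000203 (adjusted p = 0.256 with an estimated correlation). Of 5 natural killer cell markers measured, 4 were higher, and 4 adjusted over the list alone, with Gzma at least 6.20-fold, Eomes at least 4.15-fold and Gzmb at least 1.74-fold. The other 8 of the 13 on the list, the receptor genes Ncr1, Klrb1c and Klrk1 among them, were too dim in both fractions to be kept. Gzma, Eomes and Gzmb were kept through the myeloid arrays alone, a filter that favours a higher value there. By camera the list had adjusted p = 0.00737 (adjusted p = 0.356 with an estimated correlation). Dendritic cell markers did not pass as a list (5 of 10 higher and 1, Fscn1 at -2.09 ± 0.32, lower, the same adjusted over the list alone, camera adjusted p = 0.0536), although Itgax (6.18 ± 1.08) and Ccl17 (3.75 ± 0.57) were higher. The list passed under several alternatives. Nor did eosinophil, basophil and mast cell markers (4 of 8 higher and 1 lower, the same adjusted over the list alone, camera adjusted p = 0.162), where the histidine decarboxylase gene Hdc (8.87 ± 1.40) and Siglecf (at least 14.2-fold) were higher and Gata2 (-4.83 ± 0.50) was lower in myeloid cells. Cd2, Cd79b, Itgax, Ccl17 and Hdc were well above background on only 1 epithelial array, and Gata2 on only 1 myeloid array. With the other array at its floor they were at 3.83, 3.61, 5.48, 3.61, 8.76 and -4.31.

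Oxidative phosphorylation and lipid synthesis genes called over all genes were higher in epithelium, and glycolysis genes were split. Of 40 oxidative phosphorylation genes, 20 were higher in epithelial cells and 0 in myeloid cells, 32 and 0 adjusted over the list alone, among them Idh3a (at least 3.1-fold), Fh1 (-2.35 ± 0.29) and Ndufa4 (-2.11 ± 0.30) (median -0.99). In the camera test it had adjusted p = 6.1e-09 (adjusted p = 0.207 with an estimated correlation). Among families chosen after the results were seen, proteasome subunits (median -0.93), mitochondrial ribosomal proteins (-0.90) and cytosolic ribosomal proteins (-0.66) also had negative medians. A shift toward epithelium is therefore not particular to oxidative phosphorylation genes. Of 21 genes of cholesterol and fatty acid synthesis, 6 were higher in epithelium, 9 with 2 the other way adjusted over the list alone, with Scd2 (-2.44 ± 0.30), Fdps (-2.29 ± 0.27) and Idi1 (-2.26 ± 0.50) leading. For the list, camera gave adjusted p = 0.00417 (adjusted p = 0.399 with an estimated correlation). Of 31 glycolysis and hypoxia genes, 8 were higher in myeloid cells and 5 in epithelium, 13 and 6 adjusted over the list alone. The glucose transporter Slc2a3 (5.65 ± 0.40), the hexokinase Hk3 (at least 50.2-fold) and the lactate transporter Slc16a3 (4.55 ± 0.27) were higher in myeloid cells, while the hexokinase Hk2 (-1.36) and P4ha2 (-3.08 ± 0.26) were higher in epithelium (median 0.84). Camera gave the list adjusted p = 0.0179 (adjusted p = 0.395 with an estimated correlation). Slc2a3 was well above background on only 1 epithelial array, and unchanged with the other at its floor.

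Lists tied to senescence, growth arrest and Pten signalling did not pass as wholes by camera, which looks for a shift in 1 direction. By the mixed test of fry, which takes change in either direction, unadjusted p was 0.000158 for senescence-associated factors. It was 0.000526 for arrest genes and 6.79e-05 for PI3K-AKT components. That test does not compare a list with other genes, and its p was 0.0294 or lower for every list. Of 51 senescence-associated secretory factors, 13 were higher in myeloid cells and 15 in epithelium, 16 and 18 adjusted over the list alone (camera adjusted p = 0.771). Il1b, Ccl3 and the osteopontin gene Spp1 (6.13 ± 0.22) lay on the myeloid side, and Mmp3, Il6 (-4.04), the protease inhibitor Timp1 (-3.87) and Serpine1 (-3.36) on the epithelial side, with which fibroblast and matrix markers moved (17 of 21 higher there). The list median was -0.16 and the mean 0.18. Of 28 cell cycle arrest and p53 target genes, 9 were higher in myeloid and 6 in epithelial cells, the same adjusted over the list alone (camera adjusted p = 0.348). Plk3 (3.53 ± 0.69) and Gadd45b (3.04 ± 0.37) were higher in myeloid cells, and Phlda3 (-3.60 ± 0.31) and Cdkn2b, which encodes p15 (-2.63), in epithelium, while Cdkn2a (-2.11) did not pass. Of 25 proliferation genes, 4 were higher in myeloid cells and 1, Birc5 (-0.99 ± 0.23), in epithelium, 4 and 0 adjusted over the list alone (median -0.04, mean 0.35, camera adjusted p = 0.58). Lmnb1 was higher in myeloid cells by 4.86 ± 0.48, Top2a was at least 4.70-fold and Cenpa at least 3.78-fold higher, and Mki67 (0.82) did not pass. Of 26 PI3K-AKT pathway components, 5 were higher in myeloid cells and 4 in epithelium, the same adjusted over the list alone (camera adjusted p = 0.297). The leukocyte members Inpp5d (at least 33.3-fold), Pik3ap1 (5.75 ± 0.31) and Pik3r5 (at least 12.1-fold) were on the myeloid side and Pik3r3 (-2.32 ± 0.47) on the epithelial side. Of 24 androgen receptor targets, 4 were higher in epithelium and 2 in myeloid cells, 8 and 3 adjusted over the list alone (camera adjusted p = 0.0938), with Acsl3 at least 1.90-fold and Pmepa1 (-2.05 ± 0.29) higher in epithelium and Per1 (2.95 ± 0.31) higher in myeloid cells. Of 30 immediate early and dissociation genes, 5 were higher in myeloid cells and 2 in epithelium, 4 and 2 adjusted over the list alone (camera adjusted p = 0.175, passing in 4 of 17 settings), with the phosphatase gene Dusp2 at 5.06 ± 1.06, Myc at -2.76 ± 0.38 and the heat shock gene Hspb1 at -2.41 ± 0.26.

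The arrays of each fraction were not equally alike. Across the 19274 genes, the myeloid arrays correlated at Pearson r 0.992 and the epithelial arrays at 0.937, against 0.774 to 0.812 between fractions (genes are not independent replicates). The median SD per gene was 0.10 in myeloid and 0.36 in epithelial cells. Repeat spots of a probe within an array varied by an SD of 0.10 to 0.11, and over 135 probes with 10 spots the SD between arrays of the probe means was 0.07 in myeloid and 0.74 in epithelial cells, against 0.03 that spot noise alone would give. The labels describe the myeloid samples as pools, and how far their small spread reflects that between mice was not tested. On epithelial 2, compared with epithelial 1, pan-leukocyte genes were higher by a median of 1.04, macrophage markers by 1.30, MHC class II genes by 1.5, fibroblast markers by 1.39 and immediate early genes by 0.96, and luminal and basal markers had medians of -1.15 and -1.27. The same lists moved by at most 0.07 between the myeloid arrays.

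**Figure D3:**
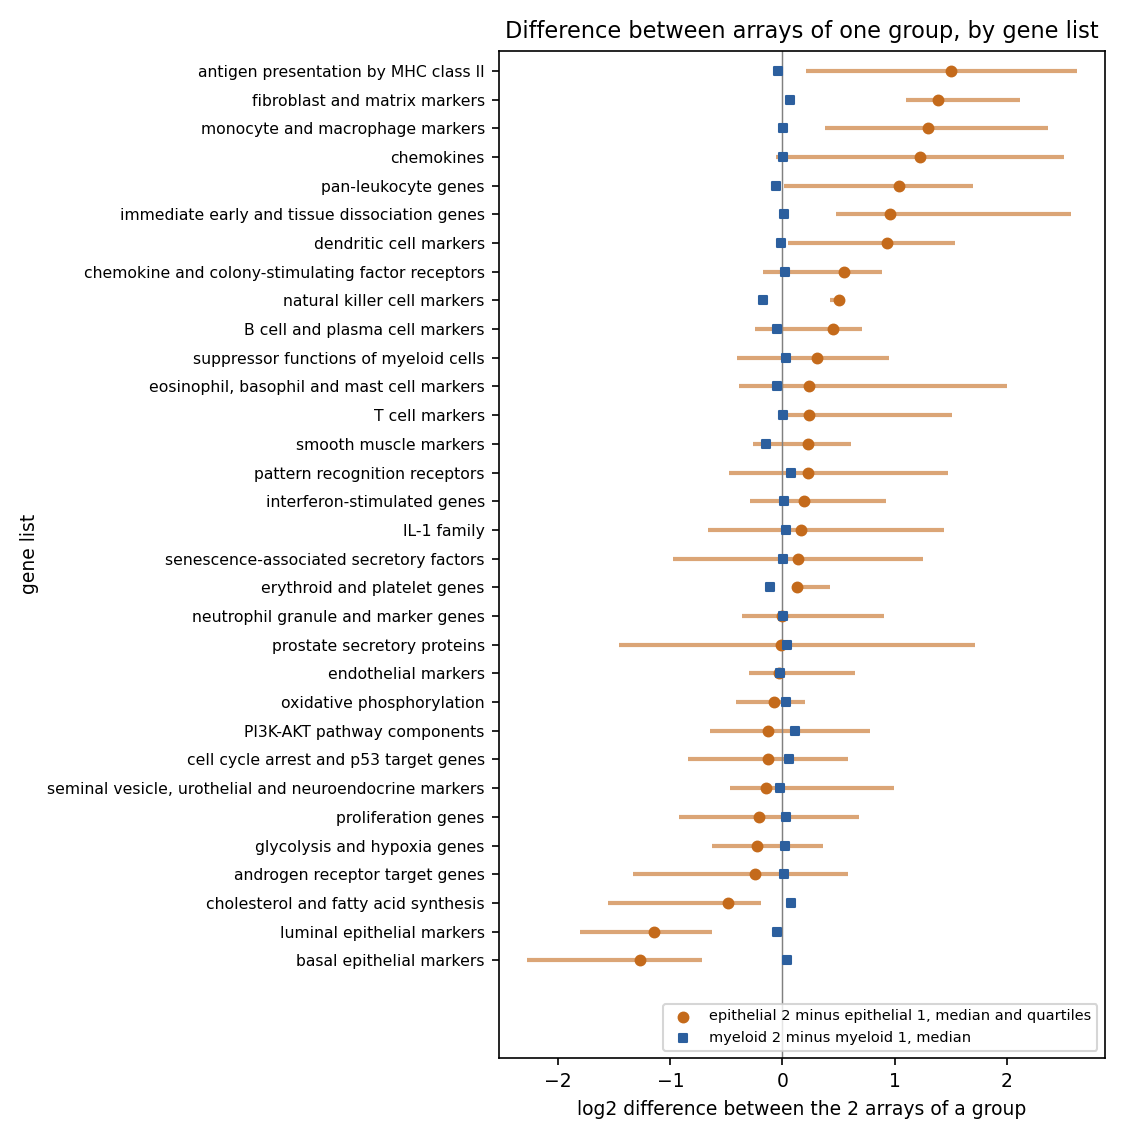
Log2 difference between the 2 arrays of a group (horizontal axis) for the tested genes of each list (vertical axis). Orange points and bars are the median and quartiles of epithelial 2 minus epithelial 1 and blue squares the median of myeloid 2 minus myeloid 1: the epithelial arrays run from -1.27 for basal markers to 1.5 for MHC class II genes.

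The number of arrays limits the precision, and the p-values measure the spread between 2 pools per fraction, which the epithelial pair dominates. Without epithelial 1 or epithelial 2 the fit called 12156 or 13226 genes, and without myeloid 1 or myeloid 2 it called 567 or 647, and 15 of 128 named calls (Krt8, Spink1, Aldh1a3, Birc5, Cldn7, Cd9, Krt17, Ccl11, Ackr3, H2-Eb1, Idh3a, Gzmb, Ptprb, Vwf and Svs1) ended under at least 1 other setting, at adjusted p from 0.0501 to 0.149 by limma.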

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

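Leaving out probes with a simple repeat was the single setting chosen after the data were seen. Of 5849 genes called, between 4914 and 5848 were called again under quantile, median or detected-probe scaling, normexp, the authors' values, averaged probes, a trended prior and probes without repeats, where totals ran from 5505 to 6078. The scaling over probes detected on all 4 arrays moved the median difference of all genes from 0.06 to 0.19 and the calls to 3093 higher in myeloid and 2594 in epithelial cells, and no filter gave 4524 calls. The numbering of the samples does not state a pairing, same-numbered deviations correlated at -0.0258 across genes, and with the replicate number as a block 5918 genes were called (2727 and 3191), 5011 of them shared. Epcam and Il1a, which did not pass without the block, were called with it at the same differences (-2.41 and 4.26, adjusted p = 0.0197 and 0.00713, limma). Restricted to genes well above background on all 4 arrays, 1454 were higher in myeloid cells, 3520 differed at least 2-fold with 1219 higher in myeloid cells, and 5 IL-1 genes passed, 4 of them higher. That filter tests fewer genes and drops those below background in 1 fraction. Normexp, with the 75th percentile or quantile normalization, left 1944 or 1909 genes at least 2-fold higher in epithelium, against 2948. The myeloid side fell too, to 1858 or 1865, against 2628, while total calls were 5774 or 5789, against 5849. Both settings add an offset of 50 to the signal, which by construction makes log2 differences smaller, most for dim genes. How much of the fall comes from the offset was not tested.

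Leaving out 1 array at a time, the lone array assumed to vary like the other group, gave 567 to 13226 calls, 458 to 6634 higher in myeloid and 109 to 6592 in epithelial cells. At least 2-fold there were 567 to 8645, 458 to 4201 and 109 to 4444. IL-1 calls ran from 6 to 23, with 6 to 20 higher and 0 to 3 lower. The low ends are fits without a myeloid array, which rest on the epithelial spread alone and ended 75 or 73 of 128 named calls.

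Of the 32 lists, 13 were called higher and 10 lower in myeloid cells, and with an estimated correlation 0 and 0 were. Arrays set 2 against 2 estimate a correlation poorly. The estimate was below the preset 0.01 for neutrophil (-0.0291), suppressor (-0.0246) and prostate secretory genes (-0.0226), and above it for others (0.774 for basal markers). All of these lists lost their call, so correlation among members does not by itself account for the loss. Fry gave 17 and 8, and other settings 11 to 15 and 8 to 10. By fry, luminal (0.0746), basal (0.0746) and cholesterol genes (0.0592) no longer passed, and proliferation (0.0102), PI3K-AKT (0.0195), androgen receptor (0.028), dendritic (0.0453) and eosinophil lists (0.00935) did. No list called in the comparison changed the direction that camera gives, which ranks a list against other genes and can differ in sign from its median. Of lists that did not pass, the senescence-associated secretory factors (median -0.163, camera down) went to camera up with normexp and the 75th percentile (median -0.0732), no filter (-0.428) and the filter on all arrays (-0.105), where the median stayed negative. Without epithelial 2 both turned (0.108, against -0.313 without epithelial replicate 1), and fry was up (adjusted p = 0.252). For the chemokines (median -0.134, camera up) camera was down with the filter on all arrays, at a median of -0.518. The immediate early genes (0.747) turned without epithelial 1 (-0.168) and passed without epithelial 2 (1.4, adjusted p = 0.000836), with normexp and quantile normalization (0.0438), no filter (0.0166) and the filter on all arrays (0.0415), with adjusted p from 0.000836 to 0.732 over all settings. With the filter on all arrays the endothelial (adjusted p = 0.2) and smooth muscle lists (0.0951) no longer passed, as the IL-1 list did not. Glycolysis genes did not pass without epithelial 2 (0.0608), nor erythroid genes without epithelial 1 or 2 (0.0583 and 0.109). Dim genes have a low signal over background, which limits these medians. The Pten probe that did not pass was called with normexp (0.87, adjusted p = 0.0279, limma) and the authors' values (0.86, adjusted p = 0.0467). In the fit of 1 value per gene, Pten also passed with detected-probe scaling (1.01, adjusted p = 0.0463) and averaged probes (1.28, adjusted p = 0.0363). Il1a passed with normexp and the authors' values (2.59 and 2.50), and Ly6g was called lower in myeloid cells with median scaling (-1.39, adjusted p = 0.0387) and the authors' values (-1.47, adjusted p = 0.0292). Over all settings, most of the range coming from leaving out an array, adjusted p ran from 0.00572 to 0.452 for Pten, 0.00226 to 0.341 for Ly6g, 0.000849 to 0.235 for Epcam and 0.000334 to 0.16 for Il1a; the cause was not tested. No named gene turned its direction.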

Other observations

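The tests of leukocyte RNA and of background signal, the gene families and their members, and the repeat-probe setting were chosen after the results were seen. Beyond the lists above, 28 gene families defined by symbol were tested for enrichment among called genes with a gene symbol, by Fisher's exact test, one-sided, adjusted over both directions. That test treats genes called in 1 fit of the same 4 arrays as independent units, which members of a family need not be. Its p-values therefore describe these calls and do not measure the spread between pools. Several receptor families of innate immune cells were enriched on the myeloid side. Of 18 C-type lectin genes 14 were higher (adjusted p = 4.37e-08), Clec4e, Clec4d, Clec7a and Clec4n most (each well above background on only 1 epithelial array), while Clec3b (-3.37) and Clec4a2 (at least 1.99-fold) were higher in epithelium. Of 11 paired immunoglobulin-like receptors 10 were higher (adjusted p = 4.02e-07), from Lilrb4a (9.10, well above background on only 1 epithelial array) to Pira6 (3.50), with Pirb at -0.02. Of 15 Siglec and CD300 genes 10 were higher (adjusted p = 4.42e-05), of 8 schlafen genes 6 (adjusted p = 0.00132, Slfn4 at least 88.7-fold), of 10 Ms4a genes 6 (adjusted p = 0.0053) and of 13 purinergic receptors 6 (adjusted p = 0.0267), among them P2rx7 (5.09), the receptor for extracellular ATP upstream of the inflammasome. The medians of these 6 families kept their sign under quantile, median and detected-probe scaling and normexp, though with normexp 3 purinergic receptors were higher in myeloid cells and 1 in epithelium. P2ry1 was at least 2.15-fold higher in epithelium.

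On the epithelial side, 15 of 27 collagens (adjusted p = 0.00132), 28 of 71 mitochondrial ribosomal proteins (adjusted p = 0.00444) and 9 of 17 tetraspanins (adjusted p = 0.0276, Tspan12 at least 5.73-fold) were enriched. The collagens share 7 genes with the fibroblast and matrix markers, 17 of 21 of which were higher in this fraction too. Cytosolic ribosomal proteins were not (12 of 75, adjusted p = 1, and from 4 to 21 called with the other scalings and normexp), nor claudins (6 of 11, adjusted p = 0.0861), Wnt ligands, receptors and antagonists (9 of 20, adjusted p = 0.0861) or keratins (9 of 30, adjusted p = 0.535). Of 11 Hox genes 5 were higher in epithelium, Hoxd13 (at least 4.07-fold), Hoxa13 (-2.63) and Hoxb13 (-2.27) among them, and the family was not enriched (adjusted p = 0.251). The medians of the epithelial-side families named here kept their sign under the same 4 settings. Of the 28 families, cadherins (0.108, and -0.00801 with median scaling) and fibroblast growth factors and receptors (-0.127, and 0.00439 with detected-probe scaling) turned, and neither was enriched.

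The epithelial arrays differed from each other far more than the myeloid arrays. Lower signal on epithelial 1 cannot be the whole cause, since among the brightest 4819 genes after quantile normalization the SD of the difference was still 4.22 times that of the myeloid pair (0.87 against 0.21). A smaller luminal share that raises all other cell types alike would move the non-epithelial lists together. Medians of 4 such lists lay 1.41 apart (permutation p = 0.0379), fibroblast markers at 1.39 and endothelial markers at -0.03. More leukocyte RNA in the second pool remains a candidate explanation for part of it. Pan-leukocyte genes were higher there by a median of 1.04, in 23 of 30 genes (exact sign test, adjusted p = 0.0278). However, 13 of the 30 were not well above background on either epithelial array, and a sort for epithelial cells would be meant to remove leukocytes. Macrophage markers moved with the pan-leukocyte genes (median 1.30), but neutrophil genes did not (-0.001, 16 of 34 higher, adjusted p = 0.987, exact sign test). T cell markers moved by 0.234 (11 of 17 higher, adjusted p = 0.688, exact sign test). The permutation and sign tests treat genes of 1 pair of arrays as independent units. Their p-values do not measure the spread between pools and cannot decide between these explanations. Among the genes that differed most, the MHC class II genes Cd74 (4.89 against 0.84) and H2-Ab1 (4.90 against 0.99), which are not on the pan-leukocyte list, were higher on epithelial 2. So were Wt1 (3.92 against 0.15) and Cxcl12 (3.22 against -0.56), while Spink1 (11.42 against 7.32) was higher on epithelial 1. A difference between the mice of the pools was not tested.

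Epithelial transcripts were measured in the sorted Gr-1+ cells. Of 34 luminal markers 33 were well above background on both myeloid arrays, although the filter could keep a gene through the epithelial arrays alone. Being well above background is how the pattern was seen, so this count cannot serve as a test against background signal of the spots. Binding of other RNA to these probes was not tested. Carry-over of epithelial RNA or cells in one proportion could put luminal and secretory genes at one ratio below the epithelium, and against epithelial 1 they were at 17.3% and 17.4% (permutation p = 0.979). Against epithelial 2 they were at 37.4% and 20.4%, a log2 difference of -0.875 (permutation p = 6e-04). This test therefore cannot tell carry-over and expression in the myeloid cells apart. Its answer turns on which epithelial array is the reference, and equal list medians do not show that single genes share a ratio. Against epithelial 1, Spink1 (3.84 on average in myeloid cells against 11.42) and Sbp (1.72 against 8.45) lay further below than Krt18 (5.68 against 9.59). Cd9 (6.27 against 5.13) lay above it.

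Some blood-cell genes, Itgam among them, looked nearly equal in both fractions through a bright probe. Of 130 kept probes with a simple repeat of at least 16 bases, 95.4% had an absolute log2 difference below 1, against 70.6% of probes matched on signal (permutation p = 1e-04, the smallest that 10000 permutations can give), which is consistent with repeat sequence binding labelled RNA of many genes. Of 24 neutrophil, receptor, T cell and pan-leukocyte genes that did not pass, 7 had another kept probe, and 5 of these passed with it (Arhgdib at 3.25, Cd247 at 2.12, Cd8a at 1.98, Itgam at 3.96 and Zap70 at 1.33). The chosen probe of Zap70 had a larger difference (2.79) that did not pass, so for the other 4 the brightest probe may understate the difference; no biological explanation was tested.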
